A study of Mus musculus with 14 samples.

How the data were processed

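The data were gene expression values of 14 single mesangial cells, the contractile, matrix-producing cells of the kidney glomerulus, taken from 1 male C57BL/6 mouse of 8 weeks and wild type. Per the labels' protocols, glomeruli were collected with magnetic beads, dissociated with enzymes and loaded on a Fluidigm C1 instrument, which captures and lyses cells in separate chambers and makes cDNA there. Every sample is 1 cell and the labels put all of them in 1 group, so no groups were compared. Cells are named by their titles, GL_M_ followed by a number.

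The deposited values are RPKM, reads per kilobase of gene scaled to the cell's read total, made by the authors. TopHat2 2.0.12 and HTSeq 0.6.1 and the genome build mm10 are named in the submitters' processing notes. The annotation release, the treatment of reads that map to several places, the read length and any filter on cells are not given in the sources used here. The table held 35271 Ensembl genes, of which 34488 matched a symbol in the GENCODE M21 gene table, and 137 of the unmatched 783 were above 0 in some cell. The 14 value columns all matched a cell title. Coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 denotes.

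RPKM values carry no read total, so the totals were recovered from the steps of the values. At low genes the ratio of a pair of cells falls on ratios of whole reads, which gave relative totals, and the smallest step of a gene with its exon length gave the absolute total. The commonest absolute total came from 2096 of 14984 genes. At genes with 1 annotated transcript, 84.7% to 89.7% of values below 50 reads per cell came out within 0.02 reads of a whole number, and 63.8% to 68.6% of these were odd, which excludes even multiples of the true totals. Common factors of the read numbers from 1 to 12 were tried, and the factor found was 1 in all 14 cells. On simulated whole reads for 14984 genes, all 14 totals came back within 0.1 percent. The totals ran from 6.60 M to 23.8 M reads. At these depths 3 reads on a transcript of 1 kb equal an RPKM of 0.126 to 0.455, depending on the cell. The cDNA was amplified and molecular identifiers are not mentioned in the labels, so this floor covers counting error only.

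A gene was called detected at an RPKM of at least 1. Levels are log2(RPKM + 1), with a pseudocount of 1, which compresses differences at low levels. Because the animal is the replicate and there was 1 animal, no p-value, standard error or confidence interval of a mean was computed from cells. Means are given with the SD over the 14 cells and describe these cells only. They are given only for genes above 0 in every cell. Where a gene is listed at 0 in some cells, the range, the median or the number of cells is given instead, since transcripts that every cell uses were also at 0. Shares of cells have exact 95% Clopper-Pearson intervals, whose upper end for 0 of 14 cells is 23.2%. They cover the sampling of 14 cells of 1 mouse and limit the share of cells with a detected transcript, not of cells that express the gene.

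Before the data were examined, 13 cell type lists and 13 functional lists were fixed, with the ribosomal protein genes (89 in the table), the mitochondrially encoded genes (13) and 5 sex-linked transcripts. All members were found except Hbb-b1 and Hbb-b2. Some lists share members, for example Gata3 and Tbx18 between the mesangial and the transcription factor lists and Acta2, Cnn1 and Tagln between the smooth muscle and the contraction lists. In each cell the mean log2 level of the mesangial list was set against that of each other cell type list. Variability was the SD over cells of log2(RPKM + 1), for 7976 genes with a mean RPKM of at least 1. The median SD of a list was placed as a percentile among 10000 random lists of the same size matched on mean level in 20 bins. In simulated tables made from these 7976 genes, 20 of 20 lists of 20 genes with halved SD fell below percentile 5, and 6 of 100 unaltered lists fell outside percentiles 5 to 95. On or off genes were those at an RPKM of at least 10 in 4 or more cells and at 0 in 4 or more cells. Of 200 such genes planted among 5000 simulated genes, all 200 were called, with 0 false calls. The other simulated genes were steady and never at 0, so this outcome followed from the rule and checks only its coding. Similarity of cells was Pearson's r across genes for the 91 pairs.

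The rule for named genes, fixed at the same time, took all mesangial list genes, the 4 highest members of each other list, undetected members, the 20 highest genes outside mitochondrially encoded and ribosomal protein genes, the 20 steadiest genes at an RPKM of at least 10 in every cell, the 20 on or off genes with the highest median where on, and the 20 genes most variable for their mean among those with a mean RPKM of at least 10. Other names are marked in the text as chosen after their values were seen. A few genes that this rule takes are not reported here.

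For 528 listed or named genes, the share of 31-base subsequences of their transcripts that also occur in transcripts of other genes, on either strand, was computed from GENCODE M21. It was at least 50% for 37 of them, whose values are uncertain. Tests of technical explanations were run on genes high in a single cell, on second lists of 22 endothelial and 22 podocyte genes, and on the variability of the proteasome list. The reads expected at on or off genes were computed as a description. Alternatives covered the detection limit, the pseudocount, 3 rescalings of the cells, the low-value filter, the measure of variability, the definition of on or off, the rank correlation and leaving out each cell. After seeing the data 3 more were added, which left out GL_M_30 with GL_M_55, left out GL_M_36 with GL_M_47, or set values below 10 to 0. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.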

Results

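The transcriptomes of 14 single cells labelled as glomerular mesangial cells, all from 1 male mouse of 8 weeks, were described as RPKM per gene. The cells form 1 group, and the questions such a series addresses are which transcripts the cells share, whether each carries the transcripts of its own type, and how far the cells differ from each other. With 1 animal, every value below describes these cells and has no biological replicate.

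Each cell had transcripts of 2955 ± 1022 genes at an RPKM of at least 1 (mean ± SD, n = 14 cells of 1 mouse), from 1770 in GL_M_60 to 5277 in GL_M_36. GL_M_36 and GL_M_47 stood above the other cells with 5277 and 4842 genes, while the remaining 12 cells lay between 1770 and 3419. The read totals, 11.8 ± 5.15 M reads, did not order the cells in the same way. GL_M_60, the most deeply sequenced cell at 23.8 M reads, had the fewest genes, and GL_M_75, at 6.60 M reads the shallowest, had 3419. Counting any value above 0 gave 6221 ± 1151 genes per cell. The 10 highest genes took 14.8% ± 2.17 of a cell's RPKM total. Mitochondrially encoded genes took 2.12% ± 0.779 and ribosomal protein genes 2.36% ± 0.402, and GL_M_91 had the lowest mitochondrial share, 0.410%. Low values were in part shared between certain cells. This was examined at 1027 genes at an RPKM of at least 100 in exactly 1 cell and below 10 in the others. In 17 of the 91 pairs the share of these genes above 0 in the other cell was at least 0.4 in both directions. The share was 0.763 on average for these pairs and 0.227 for the rest, a contrast set in part by choosing the pairs on the same genes. Where above 0, the value had a median of 0.0485% of the high cell's level in those 17 pairs and 0.0855% in the rest.

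**Figure D1:**
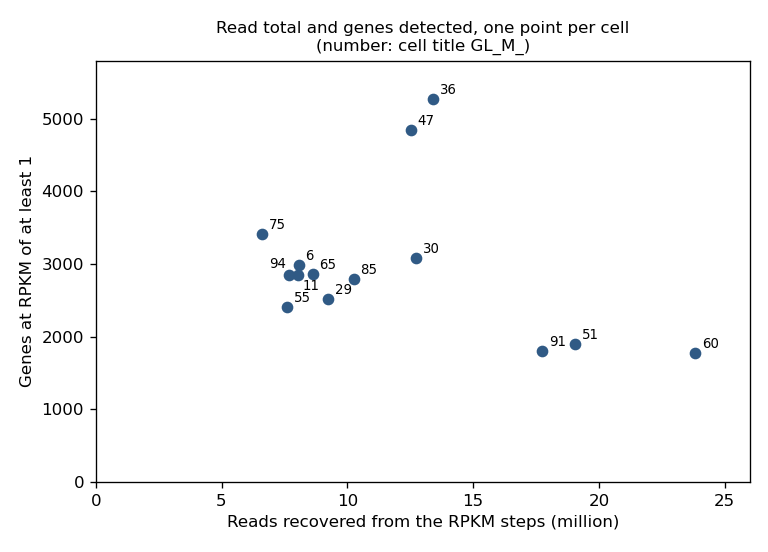
Reads recovered from the RPKM steps (M reads, horizontal) against genes at an RPKM of at least 1 (vertical), with 1 point per cell labelled by its number. GL_M_36 and GL_M_47 lie highest at 5277 and 4842 genes, and the 3 deepest cells, GL_M_60, GL_M_51 and GL_M_91, have the fewest genes, 1770, 1894 and 1810.

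Gata3, a zinc finger transcription factor, and Serpine2, a serine protease inhibitor, were the strongest transcripts of the mesangial list and were high in all 14 cells. Gata3 had a mean log2(RPKM + 1) of 12.27 ± 0.65 and ranged 4.25-fold, from an RPKM of 2518 in GL_M_30 to 10706 in GL_M_60. Serpine2 had 11.47 ± 0.90, with an RPKM of 668 to 6581. Ptn, the secreted growth factor pleiotrophin, followed at 8.93 ± 1.49, with an RPKM of 43.8 to 1508. A share of 14 of 14 cells has a Clopper-Pearson interval of 76.8% to 100%.

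The next 5 members were at 10 or more in 9 to 13 cells and lower in the rest. Itga8, an integrin chain of the mesangium, was at 7.99 ± 3.41, with an RPKM of 2902 in GL_M_91 but 0.650 in GL_M_51, and it was detected in 13 of 14 cells (66.1% to 99.8%) and at 10 or more in 12. Fhl2, a LIM domain protein, was at 7.91 ± 2.73 and at 10 or more in 13 cells, with 3922 in GL_M_60 and 0.558 in GL_M_6. Agtr1a, the angiotensin II type 1a receptor, was at 7.61 ± 2.39, at 10 or more in 13 cells but only at 1.07 in GL_M_55. Pdgfrb, the receptor for platelet-derived growth factor B, was at 5.49 ± 2.37 and at 10 or more in 12 cells, with a median over all cells of 51.7, and stayed below 1 in GL_M_29 and GL_M_30. Des, the intermediate filament desmin, was detected in 13 cells but at 10 or more in only 9, and was listed at 0 in GL_M_6. Tbx18, a transcription factor of the mesenchymal lineage, was listed at 0 in all 14 cells, which allows a share of cells with a detected transcript of up to 23.2%.

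On GRCm38, Gata3 (ENSMUSG00000015619) lies on chromosome 2 from 9857078 to 9890034 on the minus strand and Itga8 (ENSMUSG00000026768) on chromosome 2 from 12106632 to 12301922, minus. Serpine2 (ENSMUSG00000026249) is on chromosome 1 from 79794197 to 79861180, minus, Fhl2 (ENSMUSG00000008136) on chromosome 1 from 43123074 to 43196984, minus, and Des (ENSMUSG00000026208) on chromosome 1 from 75360329 to 75368579, plus. Ptn (ENSMUSG00000029838) is on chromosome 6 from 36714929 to 36810220, minus, Agtr1a (ENSMUSG00000049115) on chromosome 13 from 30336441 to 30382867, plus, and Pdgfrb (ENSMUSG00000024620) on chromosome 18 from 61045150 to 61085061, plus. Tbx18 (ENSMUSG00000032419) is on chromosome 9 from 87702800 to 87731260, minus. All 9 are annotated as protein-coding, and the values are sums over each whole gene.

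**Figure D2:**
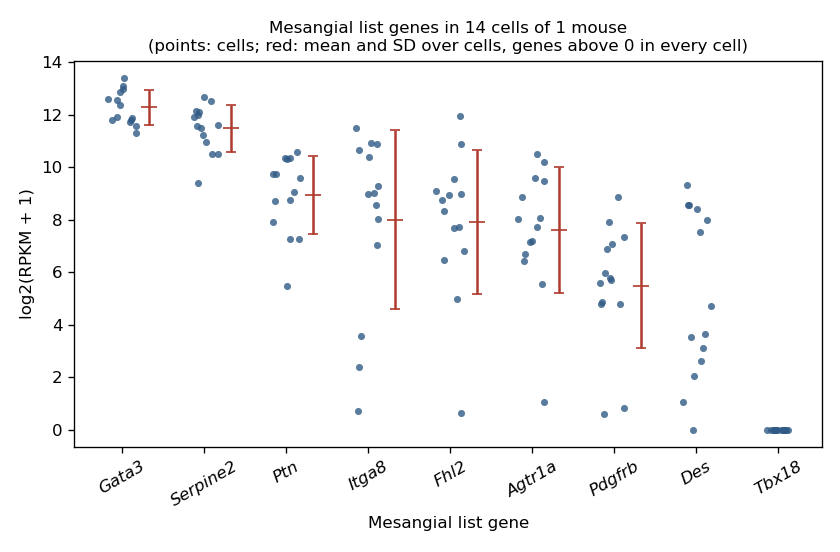
Level of each mesangial list gene (log2(RPKM + 1), vertical) in 14 cells of 1 mouse, with points for cells and red marks for the mean and SD over cells where the gene is above 0 in every cell. Gata3 (12.27 ± 0.65) and Serpine2 (11.47 ± 0.90) are tight, while Itga8, Fhl2, Agtr1a and Pdgfrb each have cells far below the rest and Tbx18 lies at 0.

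The mesangial list lay above each of the 12 other cell type lists in all 14 cells. Its mean log2 level was 7.42 ± 0.81, and the difference was smallest against the renin cell list (5.28 ± 1.63) and the endothelial list (5.29 ± 1.5). The renin cell list has only 3 genes. Its level came mostly from Rgs5, at 5.68 ± 4.08, which the pericyte list also holds, while Ren1 was at 0 in every cell. The difference was 6.03 ± 0.87 against pericytes, 6.35 ± 1.52 against podocytes, 6.75 ± 1.02 against fibroblasts and 7.01 ± 1.0 against smooth muscle. Against the lymphocyte list it was 7.23 ± 0.83, against macrophages and leukocytes 7.31 ± 0.81 and against the parietal epithelium 7.37 ± 0.87. The lists of the proximal tubule, the distal tubule with the collecting duct and the erythroid lineage gave 7.41 ± 0.81, 7.41 ± 0.81 and 7.41 ± 0.81. The lowest single differences were 1.17 in GL_M_30 for the endothelial list and 2.12 in GL_M_55 for the podocyte list. Any filter on cells is not given in the sources used here. Had cells been labelled mesangial by such transcripts, these differences would be set in part by that choice.

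Of 7 smooth muscle genes 4, and of 3 renin cell genes 2, were detected in some cell. Apart from Smtn and Rgs5, the genes of these lists were low or undetected in most cells. Acta2, smooth muscle alpha-actin, peaked at an RPKM of 1.15 and Tagln, transgelin, at 1.68, both in GL_M_30. The sequence of Tagln is shared with other annotated transcripts to 62.2%, so its level is uncertain. Actg2 reached 1.2 in GL_M_30, and Myh11, Cnn1 and Lmod1 were below 1 in all 14 cells. Smtn, smoothelin, was the exception, at 10 or more in 5 cells and up to 108 in GL_M_29. Ren1, the renin gene, was listed at 0 in every cell, and Akr1b7, an aldo-keto reductase of renin cells, was at 10 or more in GL_M_6 alone, at 28.1. Of the pericyte list, Rgs5, a regulator of G protein signalling, was at 10 or more in 9 cells, Mcam in 6, Notch3 in 4 and Cspg4 in 2, and Kcnj8, Higd1b and Anpep were listed at 0 in all 14.

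Endothelial list genes were uneven. Eng and Ehd3 were detected in all 14 cells, with RPKM of 2.42 to 928 and 1.58 to 640, and were at 10 or more in 11 cells each. Plvap, a protein of fenestral diaphragms, was at 10 or more in 8 cells and Emcn, endomucin, in 4. GL_M_30 had 10 of the 13 members at 10 or more, against 0 to 5 in the other cells. Members chosen after their values were seen include Egfl7, at 1199 in GL_M_30 and at most 0.370 elsewhere, and Cdh5, at 12.7 there and listed at 0 elsewhere. Kdr was at 127 in GL_M_30 and 34.0 in GL_M_75, Flt1 at 70.6 in GL_M_30 and 13.2 in GL_M_85, and Tie1 at 17.0 in GL_M_30 and 2.47 in GL_M_47. The members below 10 in GL_M_30, also named after their values were seen, were Pecam1 at 0.159, Sox17 at 0.0338 and Esam at 0. Esam was at 1272 in GL_M_47 and 127 in GL_M_29. GL_M_30 also had the lowest Gata3 of the 14 cells.

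Podocyte transcripts were highest in GL_M_55, where 6 of 12 members were at 10 or more, against 0 to 2 in the other cells. There Wt1 was at an RPKM of 612, Cd2ap at 421 and Synpo, synaptopodin, at 195. Thsd7a, chosen after its value was seen, was at 382 in GL_M_55 and below 1 in the other cells. Wt1 was at 10 or more in 5 cells in all. Clic3 was listed at 0 in every cell. Of 10 proximal tubule genes, 8 distal tubule and collecting duct genes and 6 erythroid genes, 0 were detected in any cell. The zeros of 4 erythroid genes are uncertain, since Hba-a2 shares 92.6% of its sequence with other transcripts, Hba-a1 75.5%, Hbb-bt 59.4% and Hbb-bs 54.4%. Fcer1g, an Fc receptor chain, was at 923 in GL_M_85 and below 10 elsewhere, and the other 10 macrophage and leukocyte genes were undetected. In the fibroblast list Pdgfra was at 10 or more in 7 cells and Pi16 in 1, while Dcn, Col1a1, Dpt and Lum were undetected. In the lymphocyte list Cd3d reached 5.62 and Ms4a1 1.93, both in GL_M_6, and the other 5 were undetected. Krt19 and Krt8 of the parietal epithelial list reached 2.24 and 1.31 in GL_M_30.

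**Figure D3:**
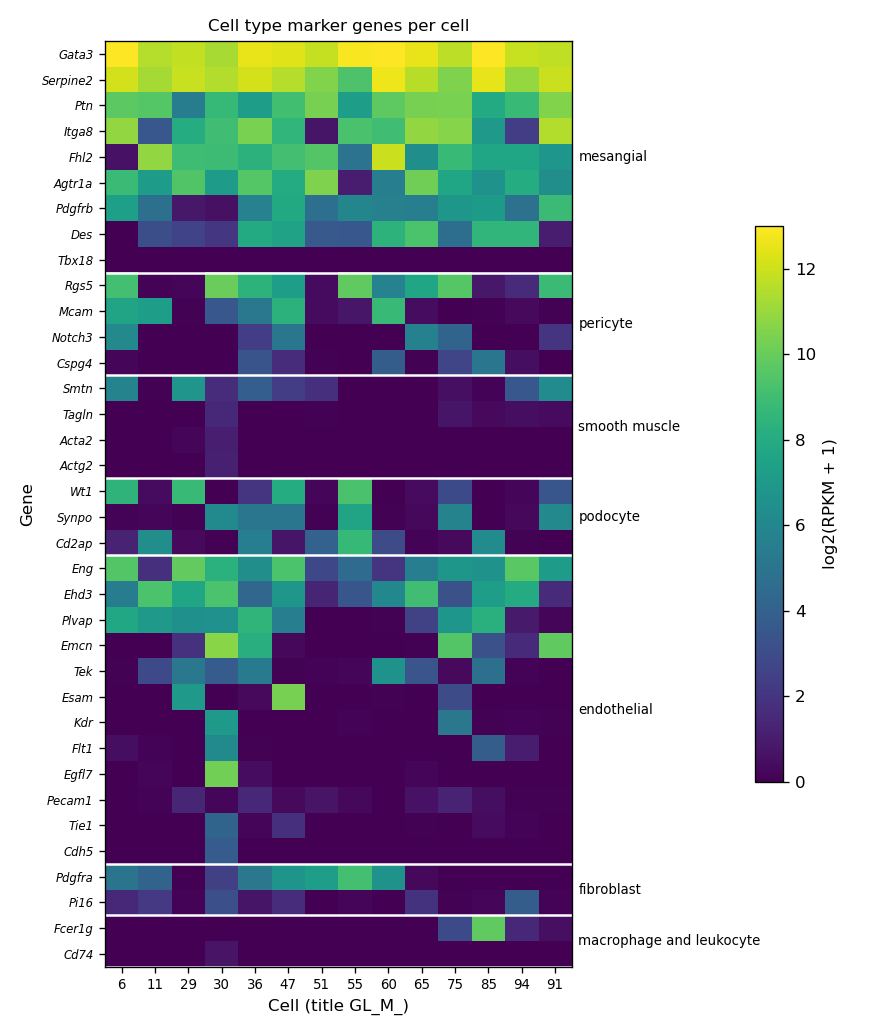
Levels (colour, log2(RPKM + 1)) of marker genes (rows, grouped by list) in the 14 cells (columns, by cell number), with the upper members of 7 lists shown. Gata3 and Serpine2 are high in every column, GL_M_30 holds 10 of the 13 endothelial genes at an RPKM of at least 10, and GL_M_55 has the highest Wt1 of the 14 cells, at 612.

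Few genes were shared by all cells. Of 10300 genes detected in some cell, 160 (1.55%) were detected in all 14 and 2947 (28.6%) in exactly 1. The 160 genes took 30.3% ± 1.82 of a cell's RPKM total, and 72 genes were at 10 or more in every cell. The number of genes detected in every cell depended on the limit, being 91 at an RPKM of at least 5, 1045 for any value above 0 and 317 for at least 13 of 14 cells. Of the ribosomal protein genes 10 of 89, and of the mitochondrially encoded genes 6 of 13, were detected in every cell. Of these 13, 7 share 62.8% to 100% of their sequence with other annotated transcripts, so this count, their share of RPKM and their variability are uncertain.

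The highest means outside these classes belonged to Actb, beta-actin, at 14.58 ± 0.33, the nuclear noncoding RNA Malat1 at 14.28 ± 0.59, Gata3, the G protein subunit Gnb1 at 12.19 ± 0.42 and the septin Sept2 at 11.93 ± 0.75. Tmsb4x, thymosin beta 4, was at 11.64 ± 0.68, Ywhaz at 11.51 ± 0.96, Pcnp at 11.17 ± 0.61, the secreted Wnt modulator Sfrp2 at 11.10 ± 0.86 and Cst3, cystatin C, at 10.97 ± 0.73. Of the 20 highest genes 19 were at 10 or more in every cell. The exception, Cbx3, ranged from 7.28 to 3637. The 20 steadiest genes had SDs of 0.33 to 0.75, and 12 of them were also among the 20 highest. They began with Actb, Myh9 (9.85 ± 0.35), the ubiquitin gene Ubb (9.87 ± 0.41), Gnb1, Actr2 (10.72 ± 0.55) and mt-Nd4 (9.12 ± 0.57), and included Ftl1 (10.21 ± 0.63), Hnrnpl (7.65 ± 0.66) and the pair Rps27 and Rps27rt. Rps27rt shares 92.7% of its sequence with other transcripts, Ftl1 64.2%, mt-Nd4 62.8%, Ubb 50.3%, Sept2 42.8% and Actb 23.6%, so their values are less certain than that of Gata3, which shares 3.83%.

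**Figure D4:**
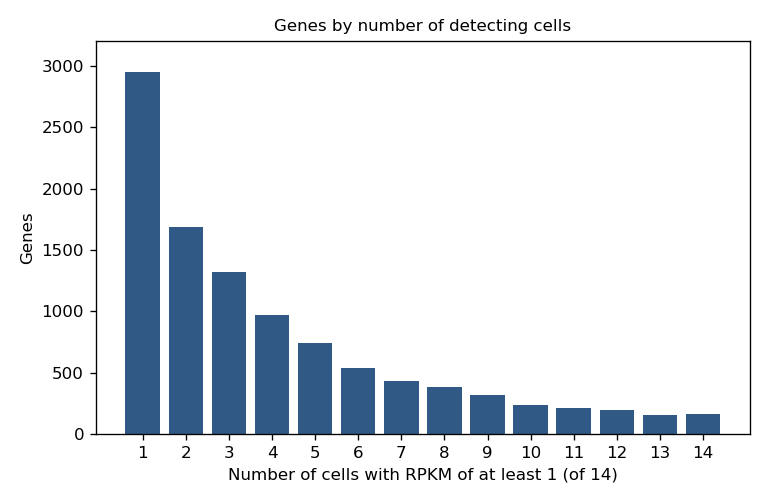
Number of genes (vertical) by the number of cells, of 14, in which they were at an RPKM of at least 1 (horizontal). The count falls from 2947 genes in exactly 1 cell to 160 genes in all 14.

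The contraction and cytoskeleton list was the highest of the 13 fixed functional lists, with 8 of 25 members in every cell. After Actb and Tmsb4x came Cald1, caldesmon, at 10.37 ± 1.12 and Myh9, non-muscle myosin heavy chain, at 9.85 ± 0.35, whose RPKM ranged only from 701 to 1571. Cnn1 was undetected. In the extracellular matrix list 2 of 35 members were detected in every cell. Igfbp7 had an RPKM of 3.56 to 1903 and Bgn, biglycan, of 3.24 to 2529, Sparc was at 10 or more in 12 cells, and Col4a1, a chain of basement membrane collagen, in 13, with a median of 107. In contrast 12 members were undetected, among them Col1a1, Col3a1, Col6a1, Col5a1, Eln, Dcn, Lum and Postn. Some other chains of these collagens, named after their values were seen, were on in part of the cells. Col1a2 and Col6a3 were at 10 or more in 4 cells each and Col5a2 in 1. Of the integrins and focal adhesion list, Itgb1 was high in every cell, at 9.05 ± 1.52, and Tns1 and Tln1 were at 10 or more in 12 and 9 cells. Ilk was listed at 0 in every cell, but 78.4% of its sequence is shared with other annotated transcripts.

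Receptors were on in part of the cells or undetected, with Agtr1a at 10 or more in 13 of 14. In the vasoactive list Gucy1a1, a subunit of soluble guanylate cyclase, was at 10 or more in 11 cells, S1pr3 in 8 and Npr3, the natriuretic peptide clearance receptor, in 9. Agtr1b, Agtr2, Adra1b, Adra1d, Ednrb, Ptger3, Tbxa2r, Cacna1c, Cacna1h and Kcnma1 were undetected. Of 19 growth factor receptors 0 were detected in every cell. Tgfbr3 was at 10 or more in 10 cells, Pdgfrb in 12, Pdgfra in 7 and Tgfbr2 in 4, and Kit and Met were undetected. Ccn2, connective tissue growth factor, was high and steady, at 9.0 ± 0.76 with an RPKM of 191 to 1069, and Timp2 was at 7.13 ± 2.27. Timp3 was at 10 or more in 11 cells and Pdgfa in 7, whereas Vegfa, Ccn1, Grem1, Igf1, Timp1 and Mmp9 were undetected.

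Among transcription factors, Gata3, Nr2f2 and Ebf1 were detected in every cell, but Nr2f2 fell to an RPKM of 1.15 and Ebf1 to 1.08 in their lowest cells. Meis2 was at 10 or more in 8 cells, and Tbx18, Foxd1, Foxc2, Srf, Prrx1, Tcf21 and Hey1 were undetected. Immediate early and heat shock genes were detected in part of the cells. Klf6 was at 10 or more in 6 cells and reached 350, Dusp1 in 5 with up to 673, Zfp36 in 4 with up to 348 and Btg2 in 3 with up to 140, and Egr1, Ier2, Ier3, Atf3, Nr4a1, Myc, Fosb and Hspa1b were undetected. Hspa1b shares 68.1% of its sequence with other transcripts. Of 17 cell cycle genes 10 were undetected, among them Mki67, Aurkb, Ccna2, Mcm2 and Mcm3. Pcna was at 1134 in GL_M_55, Cdk1 at 503 in GL_M_30, Tyms at most at 27.3 and Top2a at 8.47. B2m, the light chain of MHC class I, was at 10.20 ± 1.28, H2-D1 at 10 or more in 10 cells, and Tlr4 in 4. Il6, Tnf, Il1b, Cxcl1, Cxcl10, Ccl2, Ccl5, C3, C4b, Cd55 and Icam1 were undetected.

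Genes of general metabolism fell below an RPKM of 1 in some cells. Of 25 oxidative phosphorylation genes and 15 glycolysis genes, 0 were at 1 or more in all 14 cells, though Cox4i1, Atp5c1, Cox7a2 and Gapdh were above 0 in all 14. Cox4i1 was at 10 or more in 12, Cox7a2 in 12, Atp5c1 in 10 and Ndufa4 in 10. Aldoa, aldolase A, was at 10 or more in 11, Gapdh in 10, Ldha in 6 and Pgam1 in 3. In the proteasome list Psma3 was detected in every cell, with an RPKM of 3.52 to 2073, and Psmb6, Psma1 and Psmb5 were at 10 or more in 8, 8 and 7 cells. Psmb5 shares 71.7% of its sequence. Among ribosomal protein genes Rpl41 had a median RPKM of 619, Rps14 of 712, Rps29 of 308 and Rps27 of 258. The highest mitochondrial transcripts were mt-Cytb at 11.70 ± 1.01, mt-Atp8 at 11.30 ± 1.39, mt-Nd1 at 10.64 ± 0.75 and mt-Co1 at 9.33 ± 2.47, the last with 63.9% shared sequence.

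Against random lists matched on mean level in 20 bins, 3 of the 15 functional lists had less variation between cells than 95% of such lists and 2 had more. Genes that share a bin can differ in level. In bins of genes with a mean RPKM of at least 10, each of the 20 highest genes named above lay below its bin's median SD. The residuals ran from -0.394 (Cbx3) to -2.29 (Actb). Low percentiles of lists with very high genes, such as the mitochondrially encoded and contraction lists, are therefore not separated from level. The median SD was 1.23 for the mitochondrially encoded genes, against 2.96 for matched lists, below all 10000 of them. It was 2.98 against 3.24 for ribosomal protein genes (percentile 0.28) and 2.54 against 3.0 for contraction and cytoskeleton (percentile 2.27). The last rested on single cells. Leaving out 1 cell moved it to between 1.82 and 15.3, highest without GL_M_51 and above 5 also without GL_M_11, GL_M_30, GL_M_47, GL_M_55 or GL_M_60, and the coefficient of variation in place of the SD gave 42.3. The ribosomal percentile was 12.6 with a pseudocount of 0.1. Oxidative phosphorylation genes had a median SD of 3.69 against 3.22 (percentile 99.95), and proteasome genes 3.77 against 3.37 (98.6). By the coefficient of variation, the variability percentile of oxidative phosphorylation was 82.7. The remaining lists lay between 5.91 (cell cycle) and 93.1 (inflammation, complement and MHC). The mesangial list itself was at 6.54. Several of these crossed percentile 5 or 95 on leaving out 1 cell. Cell cycle, with 5 genes used, ran from 0.835 without GL_M_55 to 98.4 without GL_M_75, and was also below 5 without GL_M_30 or GL_M_47. Growth factor receptors reached 3.13 without GL_M_65 and 3.91 without GL_M_6, and glycolysis 97.8 without GL_M_47. Inflammation, complement and MHC ran from 89.9 to 96.8 and the mesangial list from 1.34 without GL_M_6 to 8.98, each crossing on leaving out any 1 of 8 cells.

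**Figure D5:**
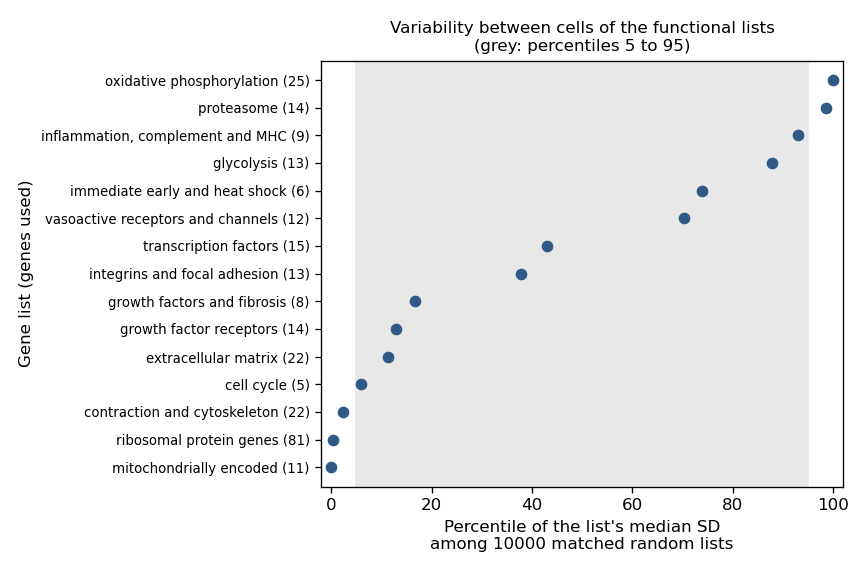
Percentile of the median SD of each functional list among 10000 random lists matched on mean level (horizontal), by list (vertical, with the number of genes used), with percentiles 5 to 95 shaded. Mitochondrially encoded, ribosomal protein and contraction genes lie below 5, and proteasome (98.6) and oxidative phosphorylation (99.95) above 95.

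At an RPKM of at least 10 in 4 or more cells and 0 in 4 or more, 676 genes were on in some cells and off in others. Among the 20 with the highest level where on, the median of the on cells ran from 468 to 822. They included Napa, a membrane fusion adaptor, with 822, Emcn with 818, Fyttd1 with 815, Sar1b with 737, the chemokine Cxcl13 with 693 and 0 in 9 cells, Casp6 with 601, the endotoxin receptor Tlr4 with 583, Rhoc with 547 and Rnase4 with 523. With fewer cells the definition is harder to meet, and the count of on or off genes was 392 to 558 on leaving out 1 cell, lowest without GL_M_36 (392) and GL_M_47 (404). It was 203 without both of these and 356 without GL_M_30 and GL_M_55. With all cells it was 235 with on at 50 and 1843 with off below 1.

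Among genes with a mean RPKM of at least 10, those most variable for their mean included Dhrs3, a retinal reductase at 10 or more in 10 cells with a median there of 1337, Sat1, which acetylates polyamines, from 0.104 to 6585, the splicing kinase Clk1 from 0.686 to 7062, St13 from 0.185 to 2286, the chromatin remodeller Atrx from 0.213 to 3076, Mfge8 from 0.314 to 2003 and Ggt5 from 0.0754 to 1761. The SDs of these 20 genes were 3.85 to 5.01 on the log2 scale.

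Across 7976 genes, Pearson's r of log2(RPKM + 1) between cells had a median of 0.29 over 91 pairs, with a range of 0.24 to 0.38. Genes are not independent replicates, so these are descriptions. By this measure no cell stood apart, since the median r of a cell with the others ran from 0.26 for GL_M_51 to 0.32 for GL_M_36. It does not single out GL_M_30 or GL_M_55, which the endothelial and podocyte lists set apart.

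Transcripts of Y-linked genes were present as in a male animal. Xist, the noncoding RNA of the inactive X chromosome, was at most at an RPKM of 0.138 in any cell. Of the 4 Y-linked genes, Kdm5d was detected in 12 cells, Uty in 10, Ddx3y in 7 and Eif2s3y in 3, and they were at 10 or more in 8, 6, 5 and 3 cells. In all, 13 of 14 cells had at least 1 of them. The exception was GL_M_60, where Ddx3y was the highest of them, at 0.709.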

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

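The alternatives without GL_M_30 and GL_M_55, without GL_M_36 and GL_M_47 and with values below 10 set to 0 were chosen after seeing the data. Of 1416 values recomputed under the alternatives, 1263 stayed within a limit set for their kind and 153 moved further. The limit was the spread between cells for levels and differences, and 1.5 times for counts. Variability percentiles had to stay on the same side of the lower and upper bounds used above, and shares of cells within the Clopper-Pearson interval. A change of sign was looked for only in the differences between the mesangial list and other lists, and 0 were found. Among 566 values that answer a comparison, 500 stayed within their limit. The cause was not tested where none is given.

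The mesangial list stayed above the others on average in all alternatives run, and the size of the difference followed the pseudocount by construction. The values that follow are those with a pseudocount of 0.1, with a pseudocount of 10 and with the median over the list's genes. For mesangial list minus pericyte list they were 7.85, 4.04 and 8.27, and for mesangial list minus smooth muscle list they were 9.36, 4.58 and 8.33. For mesangial list minus renin cell list they were 6.94, 3.53 and 7.77, and for mesangial list minus podocyte list they were 8.39, 4.21 and 8.27. For mesangial list minus endothelial list the last 2 were 3.64 and 7.66, and for mesangial list minus parietal epithelial list they were 10.13, 4.72 and 8.40. For mesangial list minus proximal tubule list they were 10.25, 4.72 and 8.41, and for mesangial list minus distal tubule and collecting duct list they were 10.26, 4.72 and 8.41. For mesangial list minus macrophage and leukocyte list they were 10.05, 4.67 and 8.41, and for mesangial list minus lymphocyte list they were 9.67, 4.69 and 8.41. For mesangial list minus fibroblast list they were 8.99, 4.45 and 8.39, and for mesangial list minus erythroid list they were 10.26, 4.72 and 8.41.

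Genes detected per cell were 6221 above 0 and 1852 with values below 10 set to 0. The genes detected in every cell were 1045 above 0, 91 at 5 or more, 317 in at least 13 of 14 cells and 72 with values below 10 set to 0. Functional list genes in every cell, 19 in all, were 54 above 0, 11 at 5 or more and 11 with values below 10 set to 0. All these follow from the definition.

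The variability percentile of contraction and cytoskeleton, 2.27, was 42.3 by the coefficient of variation, 12.1 without GL_M_30 and GL_M_55, 6.14 without GL_M_36 and GL_M_47, and 1.82 to 15.3 on leaving out 1 cell. The variability percentile of oxidative phosphorylation was 82.7 by the coefficient of variation, and that of ribosomal protein genes 12.6 with a pseudocount of 0.1.

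The number of on or off genes, 676, was 392 to 558 on leaving out 1 cell, 356 without GL_M_30 and GL_M_55 and 203 without GL_M_36 and GL_M_47, where fewer cells make the definition harder to meet. It was 235 with on at 50, 1843 with off below 1 and 2183 with values below 10 set to 0. The median correlation between cells, 0.29, was 0.39 with no filter on low values, 0.26 at a mean RPKM of at least 10, 0.26 without GL_M_36 and GL_M_47 and 0.26 with values below 10 set to 0. At 6.60 M to 23.8 M reads, depth limits values below an RPKM of 0.126 to 0.455 on 1 kb, depending on the cell.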

Other observations

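The tests of traces, of more RNA in general and of transcript loss, and the look at title numbers, were chosen after the results were seen. Those on the second endothelial and podocyte lists were written before the values of these second lists were seen. They concern GL_M_30 and GL_M_55, the cells that stood highest on the first lists. The cells form 1 group, so no biological explanation was tested.

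A few genes of the second endothelial list, which has 22 genes, were common in these mesangial cells, but most were not. The calcitonin receptor-like receptor Calcrl was at an RPKM of at least 10 in 12 of 14 cells, and Tmem204 and Icam2 were in 7 each. They were named after their values were seen, as the most widespread of the list. Every other member was at that level in at most 3 cells, and Cldn5, Sox18, Nos3 and Esm1 were listed at 0 in all 14. Of 3387 genes above 0 in a single cell only, 1064 were in GL_M_30, of which 942 were below 1, and 479 in GL_M_36.

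Genes high in 1 cell had low values above 0 more often in certain other cells. Pairs were linked on 517 of these genes, and on the other 510 the share with a value above 0 was 0.568 higher at the linked pairs (0.796, SD 0.134 over 16 pairs) than elsewhere (0.229, SD 0.0783). With all 1027 genes used, 17 pairs were linked. These followed the order of the numbers in the cell titles, with 16 of the 36 pairs at most 3 places apart linked (within GL_M_6, GL_M_11 and GL_M_29, within GL_M_36 and GL_M_47, within GL_M_51 to GL_M_65 and within GL_M_75 to GL_M_94) against 1 of the 55 pairs further apart (GL_M_60 and GL_M_91). Low expression in every cell, or the depth of the receiving cell, would give a receiving cell a like share from every source, but the share ranged by 0.733 in the median receiving cell. The range was narrowest in GL_M_30, at 0.2485, followed by GL_M_36 at 0.3272 and GL_M_47 at 0.3462, so for GL_M_30 this explanation stays open. Transfer of reads or material between certain libraries is a candidate explanation, and detections near an RPKM of 1, such as Agtr1a in GL_M_55 or Nr2f2 in GL_M_91, may be such traces. With values below 10 set to 0 the median r was 0.268 at linked pairs and 0.270 at the others, and the labels do not say what the title numbers stand for.

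GL_M_30 had the most endothelial list genes and GL_M_55 the most podocyte list genes at 10 or more, though Wt1, Synpo and Cd2ap were at that level in 5, 6 and 5 cells. On the second list, 9 of 22 endothelial genes were at 10 or more in GL_M_30, against at most 6 in another cell (GL_M_75), with Cyyr1 at 2961 and Ly6c1 at 422 but Ramp2 at 5.78 and Cldn5 at 0. Of the 9, 6 were at 10 or more in GL_M_30 alone, and 8 of the 22 were at 10 or more in some other cell. More RNA recovered in general from GL_M_30 is argued against by the 2 cells with more genes at 10 or more, GL_M_36 with 3345 and GL_M_47 with 3100 against 2017, which held 4 second-list genes each, although per 1000 such genes the count in GL_M_30, looked at before, was 1.38 times that of GL_M_75 with an exact binomial interval of 0.438 to 4.71. RNA of a second, endothelial cell in GL_M_30 may be present, as the labels name no sort that would remove it, though the margin of 9 against 6 is small. RNA of a second, podocyte cell in GL_M_55 was predicted to give it more second-list podocyte genes at 10 or more than any other cell. The second list gave 0 of 22 genes there, against 4 in GL_M_36, so the prediction failed. However, only 7 of the 22 reached 10 in some other cell. GL_M_55 had 1308 genes at 10 or more in all, against 3345 in GL_M_36. With so few genes the test cannot exclude podocyte RNA.

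Because on or off genes were defined by an RPKM of at least 10 where on, sequencing depth was set aside by the definition and not tested, and at the level of the on cells the cells at 0 would have had a median of 3476 reads. Loss of whole transcripts before amplification could contribute, but the test run cannot decide it. Proteasome subunits, which every cell uses, varied more than genes of like mean (percentile 98.6), as was known before the test was chosen. Loss would also affect the genes of like mean, so an excess over them speaks neither for it nor against it. That percentile does not separate loss from bursts of transcription or from cell states, which were not tested.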
